A study of Mus musculus with 6 samples.

How the data were processed

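RNA-seq had been done on 6 libraries labelled as embryo at E12.5, 3 wild type and 3 lnc956 knockout, from total RNA extracted with Trizol and made into libraries by standard Illumina protocols, per the labels. The deposited table gave 1 value per gene and library, taken here as FPKM calculated by the authors over each whole library. Its header names no unit: FPKM is inferred from Cufflinks being the only quantifier named and from values that are not whole, with columns of different sums. TopHat2 2.0.8, a spliced aligner, and Cufflinks 2.1.1, which estimates transcript abundance, are named with the builds mm9 and mm10, with no role given for either build, per the submitters' processing notes. FPKM divides by transcript length and by the mapped fragments of a library, so a few very abundant transcripts lower the FPKM of all others in the same library. The 10 most abundant genes held 23.1% to 30.0% of the FPKM summed over the genes of the table in wild-type libraries and 16.6% to 23.8% in knockout libraries, which are not shares of whole libraries.

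The table held 7101 genes in 2 alphabetical blocks. Of the 3644 rows of the first block all but Tuba1c had a higher mean in knockout, and all 3457 rows of the second had a lower one. It therefore appears to hold genes selected for a difference, by a rule not given in the sources used here, and genes outside it were not analysed here. The rescalings assume that most genes do not differ, which does not hold among genes chosen this way, and camera sets a list against other genes chosen this way. Adjusted p-values cover these genes alone. Counts of list members likewise cover tested members only, and members outside the table may not differ. That most tested members passed follows largely from the selection. The summed FPKM over these genes was 199529, 172788 and 170360 in wild-type replicates 1 to 3 and 291390, 304435 and 258703 in knockout replicates 1 to 3, which are not library totals. Depth in reads is unknown, so no counting interval is given. Of the 7101 symbols, 6902 matched a current gene symbol, 187 matched a synonym and 12 matched neither.

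Groups and replicate numbers were taken from the labels. Values were tested as log2(FPKM + 1), a scale that understates the change of low genes, for genes with at least 1 FPKM in at least 3 of the 6 libraries, which left out 614 genes and kept 6487. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust both on), two-sided, with genotype as the only term, Benjamini-Hochberg adjustment over the 6487 genes and a threshold of 0.05. Log2 changes are knockout minus wild type. Fixed gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 33 of 36 lists with at least 5 tested members. An exact test of 3 against 3 could not go below p = 0.1, so no single-gene exact test is given. Alternatives were other pseudocounts (0.1 and 5), filters, rescalings, limma settings and thresholds, the replicate number as a block, a Y-linked covariate, and each library left out in turn. The trimmed-mean rescaling was computed directly from its definition. The median log2 change of the genes tested was 0.38 on the deposited scale, 0.68 after trimmed-mean rescaling and 0.01 after quantile normalization. Changes are given on the deposited scale, and each named direction that turned under a rescaling is stated.

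The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM in 1 group, the 10 largest log2 increases and the 10 largest decreases. It added the 2 members of smallest p in each direction of each list, the Y-linked genes, Trim28, Hsp90b1, Mcm2 to Mcm7, Gins1 to Gins4 and Cdc45. Other members are named where a count was small or a member stood out, which was decided after the values were seen, as were Ctla2a and the lists and genes of the closing section. Some members taken by the rule are not reported here. Symbols on a list were matched to older symbols where the table used another one (4 genes). Gene positions come from GENCODE M21 on GRCm38.

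The scripts were tested on simulated data with the 6487 genes and the design of 3 against 3, with 50 genes changed at each size. Of these, 6% were recovered at a log2 change of 0.5, 52% at 1, 88% at 2 and 100% at 4, and 8 unchanged genes were called. The changed genes were drawn from those with a wild-type mean above 2 on the log2 scale. In simulated list tests over 33 lists, the 1 list that was raised was called and 0 others were. The simulated genes varied independently and nearly all were unchanged, unlike the data. The simulation therefore does not give the rate of false list calls in these data.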

Results

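RNA-seq values were analysed for 6 libraries labelled as embryo, from C57BL/6N mice at stage E12.5, a mid-gestation stage at which most organs are forming. Of these, 3 were wild type and 3 were knockout for lnc956, a long noncoding RNA. Total RNA had been extracted with Trizol from embryos at this stage, per the labels. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 7101 genes. By mean FPKM, 3643 of these genes were higher in the knockout libraries and 3458 were lower, and only 10 differed by a log2 ratio under 0.5. The genes analysed were therefore largely ones that differed between the genotypes, and the rule that chose them is not given in the sources used here. Read numbers per library were not given either. From the spacing of low values, the depth of wild-type replicates 2 and 3 was 0.94 and 1.06 times that of replicate 1, and the depth of knockout replicates 2 and 3 was 1.09 and 1.035 times that of knockout replicate 1. Depth was not compared between the genotypes in this way. Nothing in the labels says whether the replicates came from separate embryos or litters, so the p-values measure only the spread between these samples.

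The comparison asks which genes differ at this stage between libraries labelled as embryos with and without lnc956. The level of lnc956 itself was not analysed here, so the genotypes rest on the labels alone. Among the genes analysed, the libraries of one genotype resembled each other closely and those of different genotypes did not. Across genes, which are not independent replicates, the correlation of log2 values was 0.987 to 0.991 among wild-type libraries, 0.959 to 0.974 among knockout libraries and 0.284 to 0.363 between genotypes. The most abundant transcript analysed was the embryonic globin Hbb-y in each wild-type library, at 21206, 15107 and 13451 FPKM. In the knockout libraries it was the placental hormone gene Prl2c2 in replicate 1, at 14208 FPKM, and Ctla2a in replicates 2 and 3, at 14623 and 7438 FPKM. With limma, 6256 of the 6487 genes tested passed a Benjamini-Hochberg adjusted p under 0.05, 3065 of them higher and 3191 lower in knockout. Under a further requirement of a fold of at least 2 on the FPKM + 1 scale, the count higher in knockout was 2040. That scale leaves out some low genes whose mean FPKM differed over 2-fold, such as Lgals4 (2.94-fold). Of the 7101 genes, 6786 (95.6%) had groups whose values did not overlap, where chance gives 10% for 3 against 3. These counts and correlations come from genes that look selected for differing between the same groups. Such a selection lowers the correlation between genotypes and raises the share of genes without overlap. Neither therefore describes the whole transcriptome, and the counts do not give the share of it that differed.

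Most transcripts typical of placenta and decidua were abundant in the knockout libraries and low in wild type. Of the 16 tested genes on the placenta, yolk sac and decidua list, 15 rose and 1 fell (16 past the threshold adjusted over the list alone), with a median log2 change of 8.93. Prl3b1, which encodes placental lactogen II, averaged 6104 ± 880.0 FPKM in knockout and 0.67 ± 0.621 in wild type (mean ± SD, n = 3 in each group throughout). Prl8a2, a prolactin-family hormone of the decidua (the uterine lining remodelled in pregnancy), averaged 6614 ± 519.6 against 1.12 ± 0.528, and the placental protease gene Ctsj 2014 ± 501 against 0.139 ± 0.0489. The exception was Ttr, a carrier protein gene of yolk sac and liver, which fell from 60.1 ± 16.1 FPKM to 1.48, 0.0943 and 20.2 in knockout replicates 1 to 3. Rbp4, also on the list and also made in liver, passed narrowly (log2 change 0.86, adjusted p = 0.05 after rounding) and no longer passed under several settings, among them without knockout replicate 2 (0.48, adjusted p = 0.0883). The list passed camera with the preset correlation (adjusted p = 0.00017), but its adjusted p was 0.183 with an estimated correlation.

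The 10 largest increases, by the rule fixed in advance, were all genes of these tissues or of granule-bearing lymphocytes. Besides Prl3b1 (log2 change 11.89, SE 0.26, limma adjusted p = 2.2e-07), Prl8a2 (11.64, SE 0.21) and Ctsj (10.76, SE 0.20), they were the proliferin genes Prl2c2 and Prl2c5, Prl7d1, the spongiotrophoblast gene Tpbpa, and the granzyme genes Gzmd, Gzmf and Gzmg. Granzymes are serine proteases of cytotoxic lymphocytes, and the uterus in pregnancy holds natural killer cells rich in them. Gzmd averaged 3307 ± 1667 FPKM in knockout and 0.181 ± 0.0677 in wild type, Gzmf 2918 ± 1443 and 0.329 ± 0.247, and Gzmg 3432 ± 1479 and 0.689 ± 0.579. Prl7d1 averaged 2044 ± 459 and 0.209 ± 0.202. The others were uneven among knockout replicates 1 to 3: Tpbpa was at 1121, 1552 and 3965 FPKM against 0.0951 ± 0.0572 in wild type, Prl2c5 at 5083, 1378 and 1430.2 against 0.179 ± 0.123, and Prl2c2 at 14208, 2135 and 1579 against 0.449 ± 0.28. The log2 changes of these 7 genes lay between 10.71 and 11.32, each with a limma adjusted p of 6.28e-06 or lower. Closely similar copies share reads within the proliferin and granzyme families, so the division of signal among their members is uncertain.

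**Figure D1:**
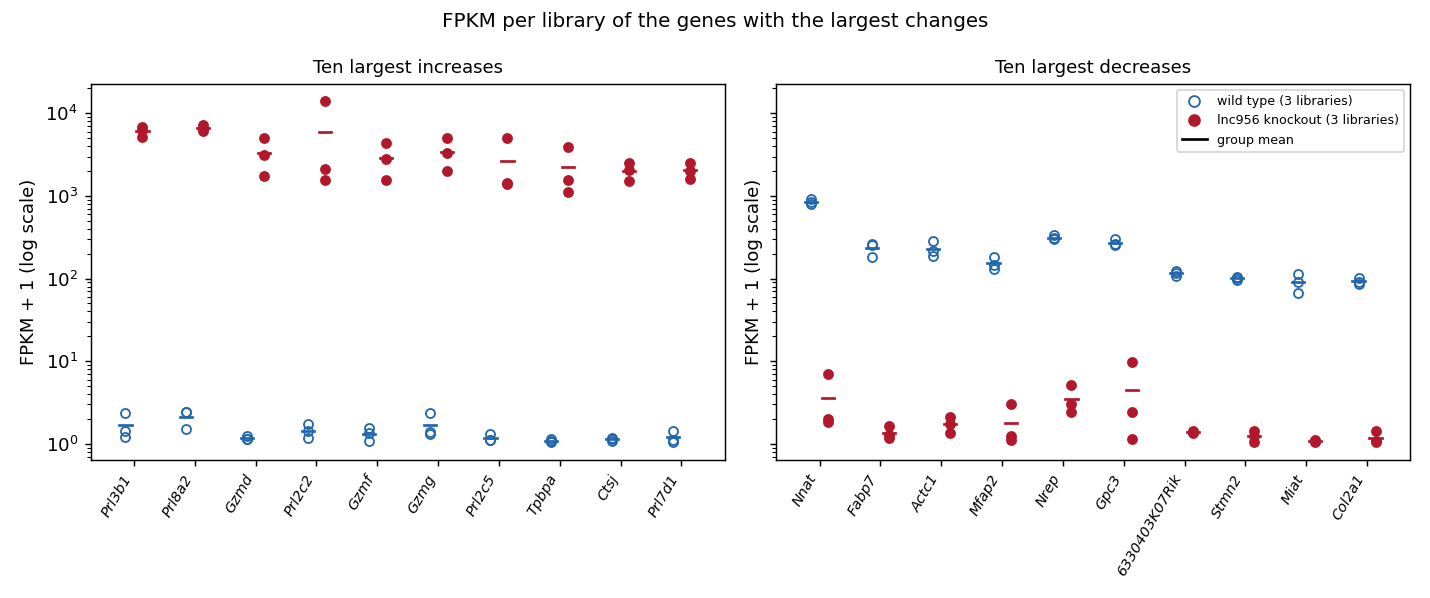
FPKM plus 1 on a log axis for the 10 genes with the largest increase (left) and the 10 with the largest decrease (right) under the fixed rule; each point is 1 library (open, wild type; filled, lnc956 knockout; 3 each) and bars are group means. Gzmd lay at a mean of 3307 FPKM in knockout and 0.181 in wild type, and Nnat at 2.59 in knockout and 848 in wild type.

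In GENCODE M21 on GRCm38, the prolactin-family genes of the table lie on chromosome 13 between 12996125 and 27808729, and Gzmb to Gzmg lie on chromosome 14 between 56117626 and 56262260. Ctsj (chromosome 13, 61000179 to 61005959) and Tpbpa (chromosome 13, 60938492 to 60941984) lie near each other. The processing notes name both mm9 and mm10, and the values came without coordinates, so these positions are those of that annotation and cover whole genes.

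Transcripts of nerve tissue were nearly missing from the knockout libraries that carried the placental and decidual transcripts. All 18 tested genes of the 30 on the postmitotic neuron list fell (18 adjusted over the list alone). The median member stood at 0.928% of its wild-type mean. In knockout replicates 1 to 3 this median was 1.22%, 0.436% and 0.988%. Stmn2, a microtubule regulator of growing axons, averaged 101 ± 4.59 FPKM in wild type and 0.236 ± 0.178 in knockout (log2 change −6.37, SE 0.16), and the neurofilament gene Nefl averaged 75.5 ± 6.78 in wild type and was at 0, 0.0524 and 0.0821 in knockout replicates 1 to 3. All 12 tested neural progenitor genes, of 25 on the list, fell as well (12 adjusted over the list alone), to a median of 1.81% of wild type. Among them were Fabp7, a radial glia gene (231 ± 43.8 to 0.367 ± 0.239 FPKM), and Msi1 (61.4 ± 5.33 to 0.109 ± 0.0611). Of 9 genes of neural crest derivatives, 8 fell and 1 rose (9 adjusted over the list alone): Ngfr fell from 20.6 ± 2.79 to 0.0965 ± 0.0396 FPKM, while Mitf, which also acts in other cell types, rose from 0.737 ± 0.137 to 56.1 ± 12.1. The neuron and neural progenitor lists passed camera (adjusted p = 4.01e-05 and 0.000256), with adjusted p = 0.183 and 0.267 with an estimated correlation. The neural crest list passed at adjusted p = 0.0433, with adjusted p = 0.36 with an estimated correlation, and its call ended with a pseudocount of 5 (0.0779), with quantile normalization (0.0885) and without any 1 of the knockout replicates (0.0507, 0.0551 and 0.0541 without replicates 1, 2 and 3).

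Muscle, heart, cartilage and limb genes were low in the same way. Of 17 skeletal muscle genes 16 fell and 1 rose (17 adjusted over the list alone), with a median of 2.23% of wild type; the actin gene Actc1 fell from 226 ± 49.6 to 0.729 ± 0.363 FPKM and the myosin gene Myh7 from 23.7 ± 3.14 to 0.29 ± 0.0702. The member that rose was Des, an intermediate filament gene of muscle that is also made in decidual stroma, from 11.3 ± 2.36 to 587 ± 249 FPKM. Of 15 heart genes 12 fell, 2 rose and Nppb did not pass (log2 change 0.17; 14 past adjusted over the list alone). The atrial genes Nppa (50.6 ± 4.26 to 0.189 ± 0.0892 FPKM) and Myl7 (69.4 ± 3.95 to 1.8 ± 0.197) fell. Hand1 rose from 2.55 ± 0.882 to 132 ± 54.7 FPKM and Hand2 from 21.1 ± 0.478 to 179 ± 21.6; these transcription factor genes act in heart and also in trophoblast giant cells (Hand1) and uterine stroma (Hand2). Of 13 cartilage genes 11 fell, led by the collagen gene Col2a1 (91.6 ± 9.18 FPKM to 0.0953, 0.0392 and 0.444 in knockout replicates 1 to 3), while Papss2 and Lect1 rose (log2 changes 1.02 and 1.11; 13 adjusted over the list alone). Of 18 limb bud and craniofacial genes 16 fell, Hand2 rose and Dlx3 did not pass (log2 change −0.04; 17 adjusted over the list alone), and Msx1 fell from 11.8 ± 0.77 to 0.141 ± 0.0692 FPKM. The 4 lists passed camera with adjusted p = 0.00071, 0.0131, 0.0151 and 0.00113 in the order given. Their values were adjusted p = 0.528, 0.408, 0.606 and 0.36 with an estimated correlation.

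The bone, tendon and connective tissue list moved both ways and did not pass camera (adjusted p = 0.307). Of its 17 genes 11 fell and 6 rose (17 adjusted over the list alone). The mesenchymal regulator Twist1 fell from 75.1 ± 10 to 0.525 ± 0.207 FPKM and the tendon regulator Scx from 22 ± 1.19 to 0.334 ± 0.245. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 3.15 ± 0.484 to 1345 ± 607 FPKM, and the proteoglycan gene Dcn from 22.8 ± 4.48 to 1027 ± 484.

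The remaining genes among the 10 largest decreases by the fixed rule were Nnat, Nrep, Mfap2, Gpc3, 6330403K07Rik and Miat. Nnat, an imprinted gene of brain and endocrine tissue, fell from 848 ± 58.3 FPKM to 0.973, 0.849 and 5.94 in knockout replicates 1 to 3 (log2 change −8.17, SE 0.48, limma adjusted p = 3.43e-06). Nrep fell from 311 ± 17.9 to 2.53 ± 1.41 FPKM, and the microfibril gene Mfap2 from 152 ± 25.6 to 0.247, 0.11 and 2 in the 3 knockout libraries in the same order. The growth-regulating glypican gene Gpc3 fell from 272 ± 24.2 to 1.45, 0.159 and 8.75 in these libraries. 6330403K07Rik fell from 115 ± 8.43 to 0.389 ± 0.0316, and the noncoding RNA gene Miat from 89.8 ± 23.9 to 0.0852 ± 0.0225. In GRCm38, Nnat lies on chromosome 2, 157560078 to 157562522, Fabp7 on chromosome 10, 57784881 to 57788450, Actc1 on chromosome 2, 114047282 to 114053548, Stmn2 on chromosome 3, 8509360 to 8561606 and Col2a1 on chromosome 15, 97975602 to 98004695. Nrep lies on chromosome 18, 33437019 to 33464029, Mfap2 on chromosome 4, 141010418 to 141015984, Gpc3 on chromosome X, 52272426 to 52613950, 6330403K07Rik on chromosome 11, 71031941 to 71033513 and Miat on chromosome 5, 112213228 to 112229395. All 10 are annotated as protein coding except Miat, a long intergenic noncoding RNA.

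Red cell and liver genes were mostly low in the knockout libraries as well. Of 23 erythroid genes 21 fell and none rose (21 adjusted over the list alone). Klf1, the master regulator of red cell genes, fell from 19.5 ± 3.46 to 0.393 ± 0.107 FPKM. Of the adult-type globins, Hba-a1 fell (log2 change −2.05, adjusted p = 0.00325), and the beta globins Hbb-b1 and Hbb-b2 did not pass. Hbb-b1 averaged 2977 ± 1488 FPKM in wild type and 3926 ± 2569.6 in knockout (adjusted p = 0.583), and the sign of its log2 change of 0.32 turned with quantile normalization (−0.83), without wild-type replicate 3 (−0.08) and without knockout replicate 1 (−0.18). Without wild-type replicate 1 it was 0.69 and without knockout replicate 3 it was 0.78. Globin copies are near-identical and their reads may be shared. Of 15 hepatoblast and hepatocyte genes 13 fell, Rbp4 rose narrowly, as given above for that gene, and Apob did not pass (13 past adjusted over the list alone). The count that fell was 10 without wild-type replicate 1, knockout replicate 1 or knockout replicate 2, and 11 under either rescaling. The list median was uneven, at 5.87%, 0.236% and 21.1% of wild type in knockout replicates 1 to 3. Vtn fell from 24.2 ± 3.8 FPKM to 0.995, 0 and 0.64 in the 3 knockout libraries. The erythroid list passed camera (adjusted p = 0.00017), with adjusted p = 0.408 with an estimated correlation. The hepatocyte list passed at adjusted p = 0.035, with adjusted p = 0.615 with an estimated correlation, and its call ended with a pseudocount of 0.1 (0.05).

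Genes of the replicative helicase were lower in every knockout library than in any wild-type library, for each Mcm and Gins gene named here. These are the libraries in which the placental list rose (median log2 change 8.93) and the neuron list stood at 0.928% of wild type, so tissue markers differed as well. In published work lnc956 has been studied together with Trim28, Hsp90b1 and the replicative helicase, which unwinds DNA at forks, so these genes were to be named whatever their values. Trim28, a corepressor gene (chromosome 7, 12999114 to 13031035), fell from 176 ± 12.3 to 30.2 ± 4.73 FPKM (log2 change −2.52, SE 0.15, limma adjusted p = 3.75e-06). Hsp90b1, an endoplasmic reticulum chaperone gene (chromosome 10, 86690209 to 86705509), was higher in knockout, at 445 ± 67.1 against 207 ± 26.5 FPKM (log2 change 1.10, SE 0.17, limma adjusted p = 0.000421). That direction turned with quantile normalization (−0.06). Mcm2 to Mcm7 fell with log2 changes from −3.56 (Mcm2, 64.9 ± 8.78 FPKM to 4.05, 2.4 and 9.08 in knockout replicates 1 to 3) to −2.53 (Mcm4, 46.2 ± 3.01 to 7.51 ± 2.83 FPKM). Gins1, Gins2 and Gins3 fell by 3.11, 2.25 and 1.46 on the log2 scale. Cdc45 and Gins4 were not analysed here. All 18 tested genes of the 27 on the helicase and licensing list fell (18 adjusted over the list alone). Their median was 16.5% of wild type (17.8%, 7.004% and 23.4% in knockout replicates 1 to 3). The list passed camera (adjusted p = 0.00207), with adjusted p = 0.615 with an estimated correlation.

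**Figure D2:**
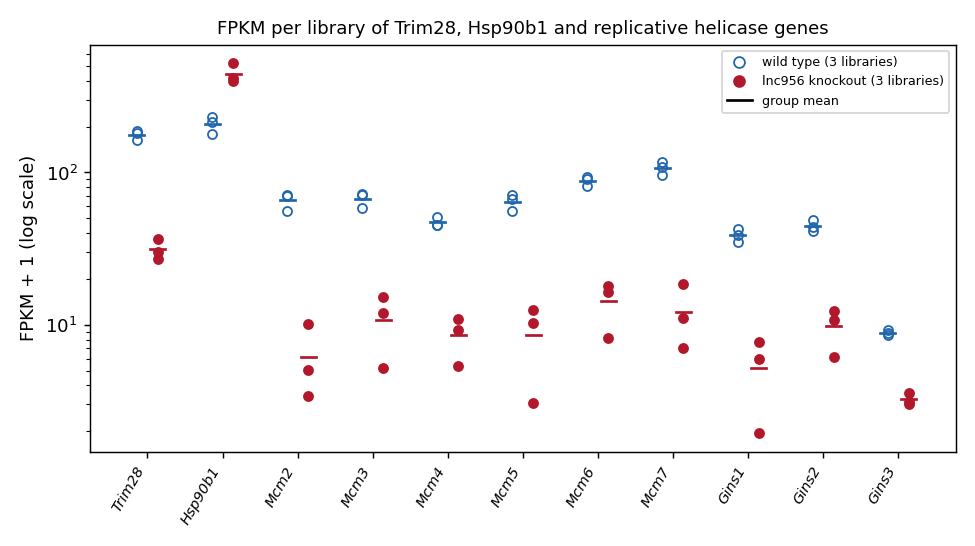
FPKM plus 1 on a log axis of Trim28, Hsp90b1, Mcm2 to Mcm7 and Gins1 to Gins3; each point is 1 library (open, wild type; filled, lnc956 knockout; 3 each) and bars are group means. Trim28 and the helicase genes lie lower in all 3 knockout libraries, and Hsp90b1 lies higher, a direction that turned with quantile normalization.

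Other genes of the cell cycle fell alongside them, in the same libraries with high placental and low nerve and muscle transcripts. All 28 mitotic genes fell (28 adjusted over the list alone), to a median of 10.5% of wild type, as in Aurkb, a mitotic kinase gene (37.4 ± 4.4 FPKM to 2.24, 1.18 and 5 in knockout replicates 1 to 3), and Nusap1 (22.7 ± 4.1 to 1.94 ± 1.08 FPKM). This median was 9.38%, 3.28% and 18.0% in knockout replicates 1 to 3, and 6.35% without replicate 3. All 17 tested DNA repair and fork protection genes, of 33 on the list, fell (17 adjusted over the list alone). Their medians were 19.3%, 5.76% and 27.0% of wild type in knockout replicates 1 to 3. Among them were Bard1 (3.85 ± 0.498 to 0.271 ± 0.176 FPKM) and Recql4 (5.07 ± 0.311 to 0.552 ± 0.289). Of 18 polymerase and fork genes 16 fell and 2 rose (18 adjusted over the list alone). The polymerase subunit gene Pola2 fell from 25.8 ± 1.02 to 4.33 ± 0.971 FPKM. Those that rose encode the subunits of ribonucleotide reductase, which makes deoxynucleotides: Rrm2 from 95.5 ± 12.8 to 543 ± 65.4 FPKM, and Rrm1 from 75.5 ± 7.41 to 109.9 ± 14.5. The Rrm1 call ended without wild-type replicate 2 (log2 change 0.45, adjusted p = 0.0564), and its sign turned with quantile normalization (−0.19). The mitotic, repair and polymerase lists passed camera at adjusted p = 0.000373, 0.00229 and 0.0187, with adjusted p = 0.615, 0.606 and 0.615 with an estimated correlation. Replication-dependent histones did not pass (adjusted p = 0.29); 8 of 11 fell, Hist1h2bc and Hist1h1c rose and Hist1h2ac did not pass (10 past adjusted over the list alone). Histone copies are closely similar and their reads may be shared.

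Interferon, immediate early and hypoxia genes were higher in the knockout libraries, the same libraries that held placental and decidual transcripts. All 29 interferon-stimulated genes rose (29 adjusted over the list alone), with a median log2 change of 3.20. Irf7, a transcription factor gene of the interferon response, rose from 0.296 ± 0.151 to 55.1 ± 7.02 FPKM, and Usp18, a brake on interferon signalling, from 0.268 ± 0.106 to 29.8 ± 2.34. All 18 tested immediate early genes, of 25 on the list, rose (18 adjusted over the list alone). Among them were Fos (0.455 ± 0.109 to 49.6 ± 16.9 FPKM) and Ier3 (2.5 ± 0.563 to 109.8 ± 36.3). All 13 tested hypoxia and glycolysis genes, of 26 on the list, rose (13 adjusted over the list alone). Among them were the vasoactive peptide gene Adm (1.17 ± 0.169 to 216 ± 57.2 FPKM) and Ndrg1 (4.39 ± 1.09 to 136 ± 10.3). The sign of Aldoa turned with quantile normalization. These 3 lists passed camera with adjusted p = 7.68e-09, 0.000119 and 0.000373. Their values were adjusted p = 0.36, 0.408 and 0.408 with an estimated correlation.

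Of 22 endoplasmic reticulum chaperone and unfolded protein response genes 21 rose in the same libraries and Trib3 did not pass (21 adjusted over the list alone). Dnajb9 rose from 10.1 ± 0.545 to 67.3 ± 7.16 FPKM and Dnajc3 from 9.78 ± 0.652 to 55.2 ± 1.95. The direction of 6 members, Atf4, Calr, Hsp90b1, Hspa5, Pdia3 and Pdia6, turned with quantile normalization, under which 13 of the 22 passed as higher and 0 as lower. Of the 20 genes on the heat shock list 7 were tested. Bag3, Cryab, Hspa1a, Hspa1b and Hspb1 rose, Fkbp4 fell and Hsp90aa1 did not pass (6 past adjusted over the list alone). Cryab, a small heat shock protein gene that is also high in decidua, rose from 15.7 ± 3.65 to 997 ± 312 FPKM. The chaperone list passed camera at adjusted p = 0.000119, with adjusted p = 0.408 with an estimated correlation. The heat shock list passed at adjusted p = 0.0391, with adjusted p = 0.394 with an estimated correlation, and its call ended with a filter of 5 FPKM (0.0602) and with quantile normalization (0.0892).

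Genes induced by the tumour suppressor p53 were mostly higher in the knockout libraries, whose placental and decidual transcripts were high and whose nerve and muscle transcripts were low. Of 19 such genes 14 rose, 4 fell and Fas did not pass (18 past adjusted over the list alone). Perp, a junction protein gene that promotes apoptosis, rose from 7.71 ± 0.964 to 38.9 ± 3.11 FPKM and Ccng1 from 8.87 ± 0.677 to 39.6 ± 8.13. Those that fell were Psrc1, Ddit4l, Ckap2 and Gtse1, of which Psrc1, Ckap2 and Gtse1 are known for roles in mitosis. The list passed camera at adjusted p = 0.0387, with adjusted p = 0.36 with an estimated correlation. Its call ended with a filter of 5 FPKM (0.0902) and without knockout replicate 1 (0.05) or 2 (0.0551). Apoptosis genes did not pass (adjusted p = 0.408); of 13, 8 rose, as in Birc3 and Pmaip1, 4 fell, as in Casp2 and Bmf, and Fas did not pass (12 past adjusted over the list alone).

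Patterning genes were mostly lower in these libraries of differing tissue markers, with some Hoxa and Hoxd genes among the exceptions. Of 27 Hox genes 20 fell and 7 rose (27 adjusted over the list alone). Those that rose were Hoxa9, Hoxa10, Hoxa11, Hoxd8, Hoxd9, Hoxd10 and Hoxd11, while Hoxa13, Hoxd13, Hoxc10 and Hoxb9 were among those that fell. Hoxa10, a regulator of uterine stroma as well as of the posterior body, rose from 8.35 ± 1.34 to 126 ± 27.9 FPKM, and Hoxa11 from 2.58 ± 0.747 to 76.4 ± 21.2. Hoxc6 fell from 16 ± 1.09 to 0.0588 ± 0.019 FPKM and Hoxa2 from 11.6 ± 0.634 to 0.146 ± 0.0649. In GRCm38 the Hoxa genes of the table lie on chromosome 6 between 52162417 and 52260880, and the Hoxd genes on chromosome 2 between 74668310 and 74765142. Of 15 Wnt pathway genes 14 fell, as in the Wnt antagonist gene Sfrp2 (63.1 ± 14.9 to 0.181 ± 0.0352 FPKM), and Wnt4 rose (log2 change 0.48, adjusted p = 0.032; 15 adjusted over the list alone). The Wnt4 call ended without any 1 of wild-type replicates 1, 2 and 3 (0.0662, 0.0825 and 0.111) or knockout replicates 2 and 3 (0.0545 and 0.0858). Of 27 Hedgehog, BMP, Fgf and Notch genes 24 fell, as in Id4 (31.1 ± 2.21 to 0.226 ± 0.0273 FPKM), and Smad7, Fgfr1 and Bmp2 rose (27 adjusted over the list alone). The Hox, Wnt and signalling lists passed camera at adjusted p = 0.0187, 0.00154 and 0.000208, with adjusted p = 0.606, 0.36 and 0.408 with an estimated correlation.

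Imprinted genes moved both ways and the list did not pass (adjusted p = 0.353). Of 20 such genes 12 fell, as in the growth regulators Mest (289 ± 21.5 to 16.1 ± 4.33 FPKM) and Grb10 (257 ± 20.4 to 30.6 ± 4.28), 6 rose, as in Impact (12.9 ± 0.643 to 31 ± 2.43), and Phlda2 and Sgce did not pass (18 past adjusted over the list alone). Cholesterol synthesis genes did not pass as a list (adjusted p = 0.43). Of 8 such genes 5 fell, as in Hmgcs1 and Mvk, 2 rose, among them Ebp, and Hsd17b7 did not pass (7 past adjusted over the list alone). Of the pluripotency genes, 4 were tested, too few for a list test: Klf2, Klf4 and Klf5 rose and Lin28b fell (4 adjusted over the list alone). None of the 30 cytoplasmic ribosomal protein genes was analysed here. Of the 27 oxidative phosphorylation genes 1 was, Ndufa1, which rose (log2 change 0.55, adjusted p = 0.00567; 1 past adjusted over the list alone), a direction that turned with quantile normalization (−0.22).

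**Figure D3:**
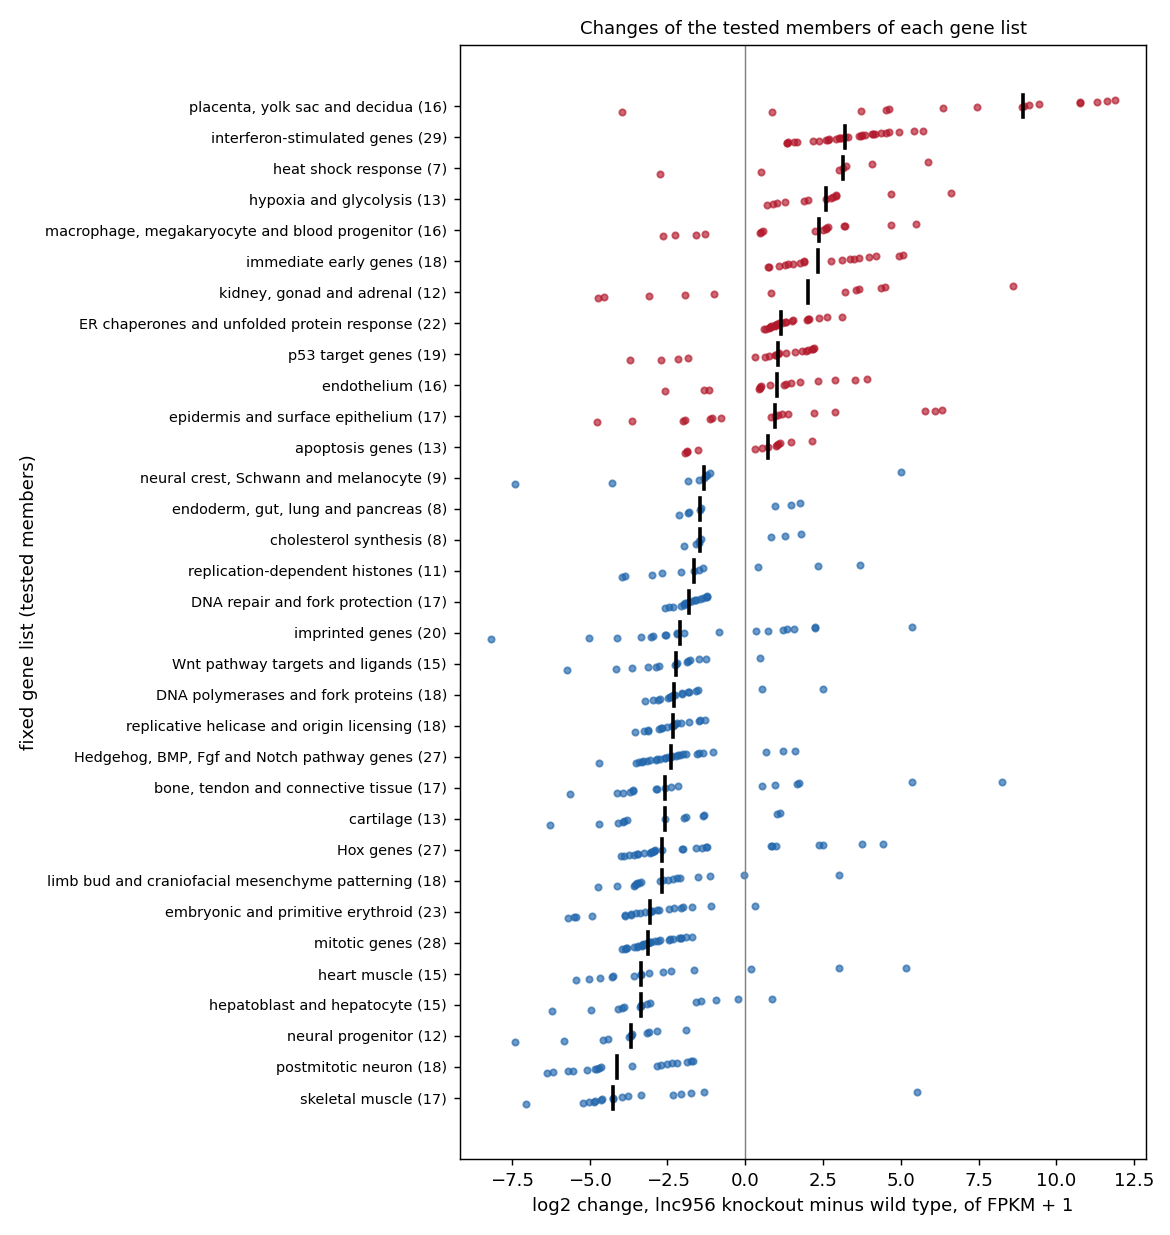
Log2 change of FPKM plus 1, knockout minus wild type, of each tested member (points) of the 33 fixed lists with at least 5 tested members; black bars are list medians, and colour gives the sign of the median. The median was 8.93 for the placenta, yolk sac and decidua list and −4.25 for skeletal muscle. Among members past the threshold, 6 chaperone genes, Rrm1, Aldoa and Wnt10b changed direction with quantile normalization. Hbb-b1, which did not pass, turned as well.

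Vessel, immune and epithelial lists held members that moved apart. Of 16 endothelial genes 9 rose, Aplnr, Sox18 and Sox7 fell, and Apln, Ecscr, Egfl7 and Emcn did not pass (12 past adjusted over the list alone). Cdh5, the endothelial cadherin gene, rose from 19.8 ± 2.6 to 308 ± 9.51 FPKM. The endothelial list did not pass camera (adjusted p = 0.0693), but passed without knockout replicate 3 (0.0228). Of 16 macrophage, megakaryocyte and blood progenitor genes 10 rose, as in the macrophage genes Cd68 (3.62 ± 0.387 to 217 ± 82.5 FPKM) and Csf1r (4.48 ± 1.18 to 144 ± 61.6). The platelet genes Pf4, Gp9 and Itga2b and the myeloid gene Mpo fell, and C1qa and C1qc did not pass (13 past adjusted over the list alone). That list passed at adjusted p = 0.0477, with adjusted p = 0.615 with an estimated correlation. Its call ended under several settings, among them both other pseudocounts (0.05 and 0.0534), and without wild-type replicate 2 or 3 (0.0631 and 0.0523) or knockout replicate 2 (0.0587).

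Of 17 epithelial genes 10 rose and 7 fell (17 adjusted over the list alone); with quantile normalization 10 rose, 4 fell and 3 did not pass. The simple-epithelium keratin genes Krt8 (14.9 ± 1.97 to 1174 ± 622 FPKM) and Krt18 (14.5 ± 1.52 to 1294 ± 564) rose, and the epidermal keratin genes Krt5 (28.1 ± 7.44 in wild type and 0.102, 0 and 0.0247 in the knockout libraries) and Krt15 (13.2 ± 4.8 to 0.0862 ± 0.0677) fell; the sign of Wnt10b turned with quantile normalization. Of 8 endoderm genes Cdx2, Sox17 and Lgals4 rose and Foxa1, Prox1, Nkx6-1, Gcg and Fabp1 fell (8 adjusted over the list alone). Of 12 kidney, gonad and adrenal genes 7 rose and Osr1, Rspo1, Six2, Pax2 and Pax8 fell (12 adjusted over the list alone). Cyp11a1, which encodes the first enzyme of steroid hormone synthesis and is also made in placenta, rose from 0.257 ± 0.052 to 499 ± 136 FPKM. The epithelial, endoderm and kidney lists did not pass camera (adjusted p = 0.353, 0.482 and 0.482).

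Of the 33 lists tested, 24 passed camera with the preset correlation, 8 higher and 16 lower in knockout. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 32 passed. Camera sets a list against the other genes tested, and here those too were mostly genes that differed.

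Y-linked transcripts, which mark male tissue, were present in 1 library of each genotype. In wild-type replicate 2, Ddx3y, Kdm5d, Eif2s3y and Uty were at 7.70, 8.51, 12.1 and 3.22 FPKM. In knockout replicate 2 they were at 2.13, 0.466, 1.90 and 0.396 FPKM. In the other 4 libraries each was listed at 0, except Ddx3y at 0.0105 in wild-type replicate 1. These genes fell below the filter on low values and were not tested. Xist was not analysed here.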

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

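The count of genes past the threshold (6256) lay between 5120, with a fold of at least 2 in FPKM + 1, and 6739 of 7101 genes, with no filter on low values. Only the count higher in knockout moved by over 1.5 times, from 3065 to 2040 with a fold of at least 2 in FPKM + 1, by construction. Leaving out 1 library at a time gave 5991 to 6282 genes, 2803 to 3099 higher and 3183 to 3195 lower. With trimmed-mean rescaling 6406 genes passed, 50.3% of them higher, and with quantile normalization 6012, 49.5% of them higher, against 49.0% as deposited. Of 5862 genes past the threshold both as deposited and after quantile normalization, 5853 kept their direction. Quantile normalization turned Hsp90b1 (−0.058), Rrm1 (−0.188), Ndufa1 (−0.215) and Hbb-b1 (−0.825). Hbb-b1, which did not pass, also turned without wild-type replicate 3 (−0.077) and without knockout replicate 1 (−0.184), within a range of −0.184 to 0.78 as libraries were left out; the cause was not tested. The lists past camera fell from 24 to 0 with an estimated correlation, which allows members of a list to vary together, and fry gave apoptosis genes the opposite direction (adjusted p = 0.551); the cause was not tested. Over all alternatives, the results of single named genes kept direction and side of the threshold in 2450 cases, lost the call in 23 and turned in 6; those of lists kept both in 473, lost the call in 43, gained it in 9 and turned in 1.

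With the replicate number as a block 6230 genes passed, 3038 higher and 3192 lower, 6193 of them also past without it; the calls of Wnt4 and Rbp4 were lost and no list call changed. The numbers are not said to pair the samples: deviations from the group means correlated at −0.055, 0.081 and 0.11 for replicates 1, 2 and 3, and not every sample correlated best with its own number, as wild-type replicate 1 did so with knockout replicate 2 (0.049). Leaving out the sex-linked genes removed no tested gene and shows nothing. The count model listed for a table of counts was not run, as the values are not counts. Depth is unknown, which leaves the precision of low values open.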

Other observations

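All tests in this part, and its gene lists other than those called fixed, were chosen after the results were seen. Other gene groups, some of which share members with the fixed lists, were raised in the knockout libraries by the limma test. None of their members past the threshold turned direction under either rescaling. Their rise describes the libraries and tests no cause, because these lists were made after the values were seen, over genes that look selected for differing. In the same libraries the placental list rose (median log2 change 8.93) and the neuron list stood at 0.928% of wild type, so tissue markers differed as well. B2m and Tap1 are also on the interferon list, Cd68, C1qa and C1qc on the macrophage list, and Cyp11a1 and Star on the kidney, gonad and adrenal list. All 16 genes of the major histocompatibility complex and its peptide loading rose (16 adjusted over the list alone, median log2 change 3.37), as in H2-K1, from 7.73 ± 0.5 to 958 ± 386 FPKM, and B2m, from 69.1 ± 7.94 to 2285 ± 1071. H2 genes are similar in sequence, so the division of reads among them is uncertain. All 25 lysosome genes rose (25 adjusted over the list alone, median 2.41), as in the cathepsin genes Ctsk (8.73 ± 3.16 to 1104 ± 547 FPKM) and Ctsl (49.5 ± 2.61 to 757 ± 140.5). Of 11 complement genes 9 rose and C1qa and C1qc did not pass (8 past adjusted over the list alone), as in the inhibitor gene Serping1 (8.72 ± 0.333 to 479 ± 194 FPKM). Of 9 steroid metabolism genes 7 rose and Fdxr and Hsd3b6 did not pass (7 past adjusted over the list alone; without knockout replicate 1, 1 of the 9 fell), as in Hsd11b1 (0.181 ± 0.124 FPKM to 138, 359.5 and 123 in knockout replicates 1 to 3).

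Globins of the first, yolk-sac-derived red cells and adult-type globins were listed apart. Hbb-y, Hbb-bh1 and Hba-x fell to a median of 2.65% of wild type (3 adjusted over the list alone; 1.75% without knockout replicate 3), with Hbb-y at 16588 ± 4084 FPKM in wild type and 364 ± 205 in knockout. Of the adult-type globins, Hba-a1 fell (log2 change −2.05, adjusted p = 0.00325) and Hbb-b1 and Hbb-b2 did not pass (1 past adjusted over the list alone), with a median of 52.7% of wild type. This median was 97.4%, 40.0% and 20.6% in knockout replicates 1 to 3, and without replicate 1 it was 30.3% and 2 of the 3 genes fell, as 2 did with quantile normalization. The difference between these globin sets was not itself tested. Of 6 yolk sac endoderm genes Apoa1, Apom, Hnf4a and Ttr fell, Rbp4 rose narrowly and Apob did not pass (3 past adjusted over the list alone); the count that fell was 2 without wild-type replicate 1, knockout replicate 1 or knockout replicate 2. Their median was uneven among the knockout libraries, at 6.18%, 0.304% and 90.3% of wild type in replicates 1 to 3.

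The pattern of most interest is that the knockout libraries held placental and decidual RNA at high levels and embryonic tissue RNA at low levels. On marker lists made after such genes had been seen to lead the increases, all 23 trophoblast, 17 decidual stroma and 11 uterine natural killer cell genes rose (23, 17 and 11 adjusted over each list alone), with the most abundant at 6104 ± 880.0 (Prl3b1), 6614 ± 519.6 (Prl8a2) and 3432 ± 1479 (Gzmg) FPKM. Wild type averaged at least 1 FPKM for 6, 13 and 1 of these genes. Of them 14, 10 and 0 are also on another list, and 2, 8 and 0 on a fixed list other than the placental one. Their rise describes the libraries and tests no source, because the genes were chosen after the increases were seen. A small admixture of placenta or decidua in otherwise intact embryos is argued against, since the neuron list reached a median of only 1.22% of wild type in the highest knockout library (1.222). A candidate explanation is that the knockout libraries were made mostly from placenta and decidua, which the lists leave open. Of the 15 fixed cell type lists other than the placental one, 9 had a median below 10% of wild type. The hepatocyte list was at 12.1% (2.94% without knockout replicate 3) and the bone, tendon and connective tissue list at 16.6%. The other 4, endothelium, macrophage, epithelium and kidney, had medians above wild type, and their cells or genes are not specific to the embryo. The rule for a placental and decidual source asked that all 15 lists lie below 10%. Lists not specific to the embryo need not fall under such a source, so that rule could not decide. Why such tissue would be there, such as loss of the knockout embryos before collection or a difference in dissection, was not tested. A change of expression inside embryonic cells that lack lnc956 is argued against as the only source of this pattern. The neuron list stood at 1.22%, 0.436% and 0.988% of wild type in knockout replicates 1 to 3, while the fixed placental list rose (median log2 change 8.93). Such a change in addition to a difference of tissue stays open, as untested.

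Y-linked RNA in knockout replicate 2 bears on the same point, since decidua is maternal and carries no Y chromosome. The measured Y-linked genes in that library stood at 27.7%, 5.47%, 15.7% and 12.3% of wild-type replicate 2 (Ddx3y, Kdm5d, Eif2s3y and Uty). That the library held no RNA of the conceptus is argued against by the lowest of these values (5.474%). Their median of 14.0% is consistent with a male conceptus mixed with RNA that lacks the Y chromosome (13.995). It rests on 1 library and on genes at low FPKM, and Y-linked genes can differ between tissues, a biological difference that was not tested. Trophoblast is tissue of the conceptus too. Its gene Tpbpa was at 1121, 1552 and 3965 FPKM in knockout replicates 1 to 3, so RNA of the conceptus does not rest on Y-linked genes alone.

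The low helicase and licensing genes were set against other cell cycle genes. A fall confined to the helicase is argued against, since all 28 mitotic genes and all 17 tested DNA repair genes fell too. The median log2 change of its 18 genes was 0.785 above that of the mitotic genes, so the mitotic genes fell further. A two-sided permutation test across genes with 100000 resamples gave p = 0.0142, but genes are not independent replicates. The helicase median (−2.335) was lower than those of the polymerase (−2.295) and repair (−1.817) lists. These are on the log2(FPKM + 1) scale, which understates the change of low genes. As percent of wild type the helicase, polymerase and repair medians lay close together, at 16.5%, 17.6% and 18.7%. In knockout replicate 2 they were 7.004%, 8.924% and 5.757%, with repair lowest. In knockout replicates 1 and 3 the helicase median was the lowest of these lists. Neither the comparison with mitotic genes nor these medians can therefore decide whether the helicase genes fell more than other cell cycle genes. Fewer cycling cells in the tissue of the knockout libraries, and a fall of these genes within cycling cells that lack lnc956, both stay open, as untested.

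In 10 splits of the 6 libraries into groups of 3, the real one included, 1 gave as many genes past the threshold as the real split (6256), and the highest of the others gave 0. For lists, 3 of the 10 splits gave as many as the real one (24), and the others gave from 16 to 24. The splits are too few for a share under 0.05. Each of the other splits also mixes the genotypes unevenly. It keeps part of their difference and puts the rest into the spread within groups. Such splits do not show what would be found without a difference, so nothing is concluded from them.

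Some genes were uneven within a group. Prl3d1, the placental lactogen I gene of trophoblast giant cells, was at 8089 FPKM in knockout replicate 1 and at 225 and 338 in replicates 2 and 3. Tfpi was at 5497 against 651 and 788 FPKM in the same libraries, and Star, a steroid synthesis gene, at 361 against 28.3 and 29.7. Rmrp, a noncoding RNA gene, was at 1142 FPKM in wild-type replicate 2 against 12.4 and 25.4 in wild-type replicates 1 and 3.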
